A study of Mus musculus with 18 samples.

How the data were processed

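RNA from the colorectum of male ICR mice, an outbred stock, was measured on Affymetrix whole-genome mouse arrays with biotin-labelled cRNA, 1 array per sample. The 18 arrays form 6 groups of 3 biological replicates. Mice were 6 weeks old at the start. Treated mice received azoxymethane (AOM), a colon carcinogen, at 10 mg/kg on day 1, and then dextran sulphate sodium (DSS), which injures the colonic epithelium, in the drinking water. DSS was given at 2% on days 8 to 14, at 1.5% on days 29 to 33 and at 1.5% on days 50 to 54, as far as each group lived to receive it. Per the labels the groups are normal mucosa of mice given saline and water (day 14), inflamed mucosa (day 14), low grade dysplasia (LGD, day 28), high grade dysplasia (HGD, day 42), high grade dysplasia with active inflammation (day 56) and carcinoma (day 140).

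The deposited values are intensity, a linear summary signal for each probe set. The submitters' processing notes name MAS5, and its version, role and settings are not given in the sources used here. Signals run from 3.39 to 24945 with a median of 56.5, and the medians of the arrays lie close together, so no further scaling was applied. The deposited table holds 45101 probe sets, of which 64 are controls. The annotation pairs 34945 probe sets with 1 gene, 932 with several genes and 9160 with none. Of those with 1 gene, 34754 matched the gene table by gene identifier, which changed 0 symbols. No genome build is named with the array files, so genes are given by symbol without coordinates. The number of arrays limits the precision of every value.

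Signals were taken to log2 after adding 16, which shrinks fold changes of dim genes. A probe set was kept when at least 3 of the 18 arrays lay above the median of the table, which left 25041. Each gene was represented by its probe set with the highest mean over all arrays, giving 12878 genes. For 5429 of these genes more than 1 probe set passed, and 1459 genes rest on probe sets that the manufacturer marks as able to bind related transcripts. Control probe sets and probe sets with several genes or none were left out of the main tests and counted apart.

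Group means were compared with limma 3.58.1 in R 4.3.3. All 18 arrays entered 1 model with 12 residual degrees of freedom, and the spread of each gene was moderated with an intensity trend (median prior degrees of freedom 2.51). Each of 5 stages was compared with normal mucosa, and 5 further comparisons were made between stages. P-values are 2-sided and adjusted by the Benjamini-Hochberg method over all genes within a comparison, with a threshold of 0.05. A moderated F test asked which genes differ among the 6 groups. Standard errors (SE) come from the model, standard deviations (SD) from the 3 arrays of a group, and n is 3 per group throughout.

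The tests, the comparisons, 33 gene lists and the rule for naming genes were set before the data were examined. For each comparison with normal mucosa the rule takes the 8 genes with the largest increase and the 8 with the largest decrease among those that passed with all 3 arrays of one group beyond all 3 of the other, and for each comparison between stages 5 and 5. From each list it takes up to 4 members with the largest change among those that passed, or the member with the smallest p where none passed. Axin2, Ptgs2, Myc, Car4, Muc2 and Mki67 are always included, and predicted genes without a name are passed over. Genes named outside the rule are identified as such.

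The lists cover neutrophils, macrophages and monocytes, mast cells, T cells, B and plasma cells, inflammatory cytokines and chemokines, NF-kB feedback and targets, STAT3 and epithelial defence, the interferon response and eicosanoid enzymes and receptors. Of signalling and growth they cover Wnt/beta-catenin targets, MAPK feedback and targets, immediate early genes, the cell cycle, the p53 response, and hypoxia and glycolysis. Of epithelium they cover regenerative epithelium, mature colonocytes, goblet, enteroendocrine, tuft and Paneth cells, fatty acid oxidation and ketogenesis, and xenobiotic metabolism. Of other tissue they cover extracellular matrix and fibroblasts, matrix proteases and inhibitors, endothelium, smooth muscle, enteric neurons and glia, squamous epithelium, adipocytes, erythroid cells and pancreatic acini. Alox5 and Ptgs1 are on both the eicosanoid and tuft lists, Cyp2c55 on the colonocyte and xenobiotic lists, Mmp7 on the Wnt, Paneth and protease lists, and Mmp8 and Mmp9 on the neutrophil and protease lists. The 28 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Beside each list call that is given stands the result with an estimated correlation, and for most of them the members that passed are counted over all genes and adjusted over the list alone. A further list of 15 general epithelial genes was chosen after the data were examined but before its own values were seen, and it shares 0 genes with the other lists.

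RNA quality was read from the 3 prime to 5 prime log2 ratios of the Gapdh and beta-actin control probe sets and from the 18S control probe sets, with exact or sampled permutation tests. The procedure was tested on simulated data, drawn from the mean and moderated spread of each gene, with 200 genes shifted. At 2-fold, 72% to 83% of the shifted genes were recovered in the 10 comparisons, and at 4-fold 93% to 98%, with 6 to 12 false calls and 0 calls of the wrong sign. The simulated genes were independent, with the same spread in all groups and no outlying arrays. In the real groups the median SD over genes ran from 0.131 in normal mucosa to 0.206 in HGD at 8 weeks. These rates therefore check the procedure and need not hold for the real comparisons.

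Alternatives covered other pseudocounts, filters, scalings and summaries of probe sets, no intensity trend, array weights, the replicate number as a block, a 2-fold minimum, fits on only the 6 arrays compared, and each array left out in turn. Leaving out LGD replicate 3 and HGD 8-week replicate 1 together was added after seeing the data. The planned array weights were computed gene by gene, because the default method did not converge, and this change also came after seeing the data. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.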

Results

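Gene expression was measured in colorectal mucosa from the AOM and DSS model of colitis-associated cancer, in 6 groups of 3 arrays each. The groups are normal mucosa, inflamed mucosa at 2 weeks (the last day of the first DSS cycle), low grade dysplasia (LGD) at 4 weeks, high grade dysplasia (HGD) at 6 weeks, high grade dysplasia with active inflammation at 8 weeks (2 days after the third DSS cycle) and carcinoma at 20 weeks. All normal mucosa came from day 14, so for the 4 later stages the stage and the age of the mice differ together. The first principal component held 53.2% of the variance. Of 12878 genes tested, 5840 differed among the 6 groups by limma's moderated F test. With only 3 arrays per group, the number of arrays limits the precision, and for the stages after 2 weeks the counts of genes changed against normal mucosa moved several-fold when single arrays were left out.

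The comparison of inflamed with normal mucosa at 2 weeks asks what AOM and the first DSS cycle change together. It is the one stage with controls of its own age. Normal mice received neither, and no group received AOM or DSS alone, so their effects cannot be told apart. Neutrophil and acute inflammatory genes showed the largest increases. S100a9, a subunit of the neutrophil protein calprotectin, rose from 5.75 ± 0.69 to 14.18 ± 0.48 on the log2 scale (SD, n = 3 per group). This was a log2 change of 8.43 ± 1.40 (SE, adjusted p = 2.05e-04). Its partner S100a8 rose by 7.89 ± 1.30, the chitinase-like protein gene Chil3 by 7.74 ± 1.43, the chemokine genes Cxcl5 by 7.61 ± 1.05 and Cxcl2 by 7.11 ± 1.33, and the acute phase genes Saa3 by 6.92 ± 1.07 and Hp by 6.71 ± 1.09. All 14 measured neutrophil markers rose (14 adjusted over the list alone), with a median log2 change of 4.52 (camera adjusted p = 4.61e-06, and adjusted p = 0.346 with an estimated correlation).

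Of 18 inflammatory cytokines and chemokines, 15 rose (16 adjusted over the list alone), among them Il6 by 6.67 ± 0.90 (camera adjusted p = 2.19e-06, and adjusted p = 0.331 with an estimated correlation). Of 16 macrophage and monocyte markers, 15 rose (15 adjusted over the list alone, camera adjusted p = 5.52e-09, and adjusted p = 0.211 with an estimated correlation). The scavenger receptor genes Marco and Cd163 had log2 changes of 5.61 ± 0.19 and 3.36, and the other probe set of Marco had 2.77. Of 14 NF-kB feedback genes and targets, 11 rose (11 adjusted over the list alone), such as the adhesion molecule gene Icam1 by 2.47 ± 0.28 (camera adjusted p = 9.32e-05, and adjusted p = 0.331 with an estimated correlation). In the STAT3 and epithelial defence list of 14, 8 rose and 1 fell (8 and 2 adjusted over the list alone). Lcn2, an iron-sequestering antimicrobial protein gene, rose by 6.63 ± 1.07, and Pigr, the receptor that carries immunoglobulin across the epithelium, fell by 4.52 ± 1.05 (camera adjusted p = 0.00123, and adjusted p = 0.348 with an estimated correlation). Of 13 eicosanoid genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0241, and adjusted p = 0.331 with an estimated correlation). Prostaglandin synthase genes Ptges and Ptgs2 rose by 3.12 ± 0.42 and 3.19 ± 1.02, and Hpgd, which degrades prostaglandins, fell by 3.76 ± 0.44. Of 13 immediate early genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0241, and adjusted p = 0.442 with an estimated correlation). That call was lost without inflamed replicate 3 (adjusted p = 0.0618).

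Genes of differentiated epithelium showed the largest decreases at 2 weeks. Mptx1, a mucosal pentraxin gene, fell by 7.19 ± 1.53, as did the antimicrobial ribonuclease gene Ang4 (-6.58 ± 0.82), the mucus-associated Clca1 (-6.24 ± 1.17) and Reg4 (-5.98 ± 0.68). Of 15 goblet cell genes, 14 fell (14 adjusted over the list alone) with a median log2 change of -3.93, including the mucin gene Muc2, which fell by 4.20 ± 0.90 (camera adjusted p = 2.05e-06, and adjusted p = 0.331 with an estimated correlation). Of 21 mature colonocyte genes, 17 fell (18 adjusted over the list alone), such as the chloride-bicarbonate exchanger gene Slc26a3 (-5.13 ± 1.37) and the water channel gene Aqp8 at -4.90 ± 1.11 (camera adjusted p = 5.11e-06, and adjusted p = 0.331 with an estimated correlation). Car4, a carbonic anhydrase gene, had a log2 change of -3.07 ± 1.41 and did not pass (adjusted p = 0.0886). Of 15 xenobiotic metabolism genes, 14 fell (14 adjusted over the list alone), led by the glucuronosyltransferase gene Ugt2b34 at -5.10 ± 0.61 (camera adjusted p = 3.3e-06, and adjusted p = 0.331 with an estimated correlation). Of 15 fatty acid oxidation genes, 11 fell (11 adjusted over the list alone), and the coactivator gene Ppargc1a fell by 3.25 ± 0.42 (camera adjusted p = 5.62e-05, and adjusted p = 0.211 with an estimated correlation). Beside these lists, 15 of 15 general epithelial genes fell, with a median log2 change of -3.03, from -3.54 for Vil1 to -2.01 for Esrp2. Their mean against normal mucosa was -1.33, -4.92 and -2.59 in inflamed replicates 1, 2 and 3.

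Cell cycle genes also fell at 2 weeks. Of 27 cell cycle genes, 16 fell (16 adjusted over the list alone), such as the ubiquitin-conjugating enzyme gene Ube2c (-1.29 ± 0.20) and the proliferation marker Mki67 at -0.86 ± 0.19 (camera adjusted p = 6.92e-04, and adjusted p = 0.489 with an estimated correlation). Of 14 matrix proteases and inhibitors, 13 rose (13 adjusted over the list alone), including the metalloproteinase genes Mmp3 by 6.70 ± 0.83 and Mmp10 by 6.09 ± 0.76 (camera adjusted p = 2.05e-06, and adjusted p = 0.283 with an estimated correlation). Of 17 extracellular matrix and fibroblast genes, 13 rose (14 adjusted over the list alone), led by the tenascin gene Tnc by 3.15 ± 0.45 (camera adjusted p = 5.2e-06, and adjusted p = 0.331 with an estimated correlation). Endothelial markers rose in 9 of 10 cases (9 adjusted over the list alone), Plvap by 2.02 ± 0.23 (camera adjusted p = 5.31e-06, and adjusted p = 0.211 with an estimated correlation). Enteric neuron and glia markers rose in 9 of 10 cases (10 adjusted over the list alone), Uchl1 by 2.34 ± 0.33 (camera adjusted p = 5.23e-05, and adjusted p = 0.211 with an estimated correlation). Smooth muscle markers gave 0 calls among 12 by limma, over all genes and adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.214), and a fit on only the 6 arrays called 6 lower. The 18S control signal was 9.23 ± 0.95 in inflamed and 10.87 ± 0.36 in normal mucosa (SD, n = 3; exact permutation p = 0.1, the smallest possible).

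The other tested lists did not pass at 2 weeks. Wnt/beta-catenin targets had a median of -0.20, with 1 of 21 higher, Cd44 by 1.78 ± 0.28, and 2 lower, Rnf43 (-1.70 ± 0.58) and Ccnd1 (-0.91 ± 0.26, camera adjusted p = 0.667). Axin2 (-0.99 ± 0.70, adjusted p = 0.267) and Myc (-0.18 ± 0.19, adjusted p = 0.47) did not pass. Camera adjusted p was 0.777 for the interferon response (2 of 23 higher), 0.0807 for T cells (2 of 11 higher), 0.461 for B and plasma cells (1 of 13 higher), 0.182 for MAPK targets (5 of 12 higher and 1 lower), 0.926 for the p53 response (4 of 15 higher and 5 lower) and 0.0987 for hypoxia and glycolysis (5 of 16 higher and 2 lower). For mast cells it was 0.586, with 1 of 11 higher, the histidine decarboxylase gene Hdc. It was 0.0978 for regenerative epithelium (6 of 12 higher and 1 lower), 0.875 for enteroendocrine cells (2 of 9 higher and 1 lower, with a median of -0.27 and a test pointing upward) and 0.777 for squamous epithelium (1 of 7 higher). Here and in the other comparisons, lists whose median, mean and test differed in sign were not called. The lists with under 5 measured members were not tested. Of these, 3 of 4 tuft cell genes (Dclk1, Alox5 and Hpgds) and 1 of 1 erythroid gene (Alas2) were higher. Dclk1 had a log2 change of 2.08, and its 4 other probe sets ran from 0.06 to 1.96. Whether tuft cells changed in number was not tested. Of the 4 Paneth cell genes 1 was higher (Lyz1) and 1 lower (Itln1), and 1 of 4 adipocyte genes (Pck1) and 1 of 4 acinar genes (Cela1) were lower.

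In all, 2903 genes were higher and 3131 lower in inflamed mucosa, 6034 together, and 2463 changed at least 2-fold. The 3 arrays of one group lay beyond all 3 of the other for 60.2% of genes, where chance gives 10%. Of 110 genes taken by the naming rule that passed, 102 passed whichever single array was left out.

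**Figure D1:**
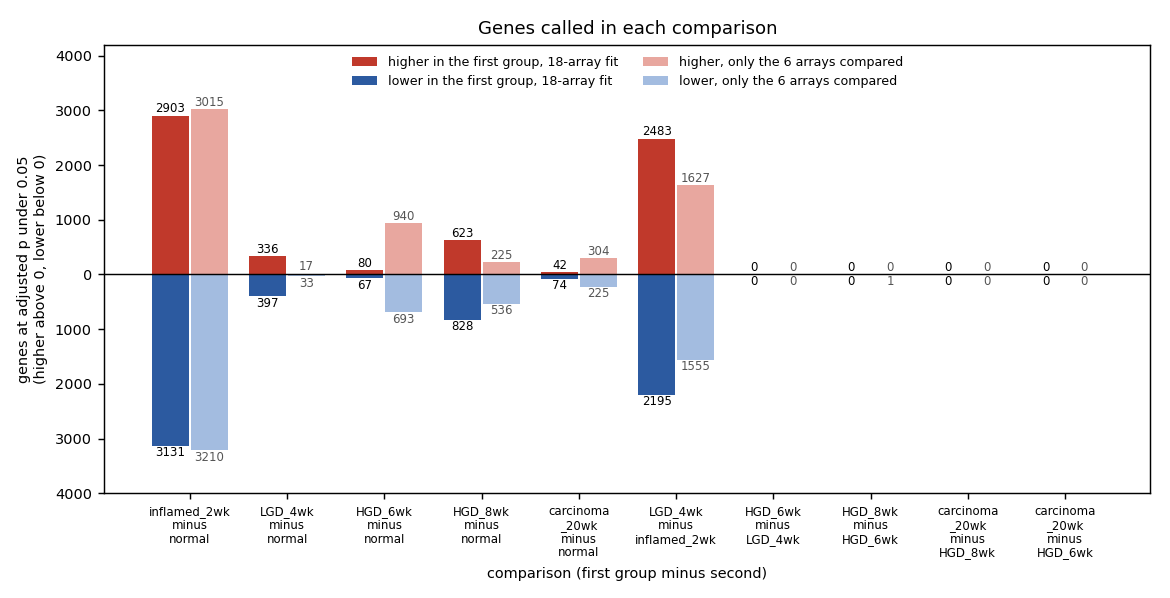
Bars give the number of genes called higher (above 0) and lower (below 0) at an adjusted p of 0.05 in each of the 10 comparisons, dark for the model on all 18 arrays and light for fits on only the 6 arrays compared. Inflamed against normal mucosa gave 6034 genes and LGD against inflamed mucosa 4678, while the later comparisons between stages gave 0 with all 18 arrays.

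LGD at 4 weeks against normal mucosa asks what distinguishes the first dysplastic lesions. Sptssb, which encodes a small subunit of the enzyme that starts sphingolipid synthesis, rose by 3.40 ± 0.45 (SE, n = 3 per group, adjusted p = 0.00298), and the myosin light chain gene Myl7 by 3.11 ± 0.42. The other probe set of Sptssb had a log2 change of 1.32. S100a9 rose by 5.34 ± 1.40 (adjusted p = 0.0407) and S100a8 by 5.09 ± 1.30. Defa31, an alpha-defensin gene measured on a probe set that may also bind its relatives, rose by 4.94 ± 1.27, and Wfdc18 by 3.15 ± 0.54. The gluconeogenesis gene Pck1 fell by 3.22 ± 0.53, and Slc37a2, a sugar phosphate transporter gene of colonocytes, fell by 3.03 ± 0.47 (adjusted p = 0.00607). Ppara, the nuclear receptor that drives fatty acid oxidation, fell by 0.90 ± 0.09 (adjusted p = 4.09e-04).

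Of 21 Wnt/beta-catenin targets, 1 rose in LGD, Cd44 by 1.46 ± 0.28 (1 adjusted over the list alone), while the median of the list was 1.46 (camera adjusted p = 6.51e-06, and adjusted p = 0.402 with an estimated correlation). Its mean against normal mucosa was 2.38, 1.91 and 0.26 in LGD replicates 1, 2 and 3. With only the 6 arrays fitted, 0 of 21 were called. Axin2 had a log2 change of 1.56 ± 0.70 and did not pass (adjusted p = 0.188), nor did Myc (0.41, adjusted p = 0.199). Of 27 cell cycle genes, 7 rose, led by the replication helicase gene Mcm3 by 0.91 ± 0.24 (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.27e-07, and adjusted p = 0.382 with an estimated correlation). Of 14 proteases and inhibitors, 4 rose, including Mmp10 by 3.26 ± 0.76 and the inhibitor gene Timp1 by 2.36 ± 0.49 (11 adjusted over the list alone, camera adjusted p = 1.27e-07, and adjusted p = 0.301 with an estimated correlation). Neutrophil markers had 2 of 14 higher (6 adjusted over the list alone, camera adjusted p = 6.51e-06, and adjusted p = 0.382 with an estimated correlation). Their mean ran from 0.51 to 4.92 across the 3 LGD arrays. STAT3 and epithelial defence had 2 of 14 higher (8 adjusted over the list alone, camera adjusted p = 3.35e-04) and macrophages 1 of 16 (3 adjusted over the list alone, 7.55e-04), and both had an adjusted p of 0.382 with an estimated correlation. The call for cytokines and chemokines (9.97e-04, and adjusted p = 0.466 with an estimated correlation) was lost without LGD replicate 1 (adjusted p = 0.133). Extracellular matrix genes had 3 of 17 higher, Col4a1 by 1.04 ± 0.24 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.96e-04, and adjusted p = 0.382 with an estimated correlation).

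Of 15 xenobiotic metabolism genes, 6 fell in LGD (10 adjusted over the list alone), such as the sulphotransferase gene Sult1a1 at -2.69 ± 0.62 (camera adjusted p = 3.46e-08, and adjusted p = 0.301 with an estimated correlation). Of 15 fatty acid oxidation genes, 4 fell (9 adjusted over the list alone, camera adjusted p = 1.48e-07, and adjusted p = 0.185 with an estimated correlation). Of 21 colonocyte genes, 1 fell, Slc37a2 (1 adjusted over the list alone, median -1.08, camera adjusted p = 4.41e-05, and adjusted p = 0.382 with an estimated correlation). Enteroendocrine genes had 0 calls among 9 by limma (7 adjusted over the list alone), with a median of -1.41 and Chga, a hormone granule protein gene, at -1.41 ± 0.55 (camera adjusted p = 6.63e-04, and adjusted p = 0.382 with an estimated correlation). Goblet cell genes had 1 of 15 lower, the lineage factor gene Atoh1 at -1.32 ± 0.35 (2 adjusted over the list alone, camera adjusted p = 0.0111, and adjusted p = 0.518 with an estimated correlation). That call was lost without normal replicate 3 or LGD replicate 1 (adjusted p up to 0.0759). Muc2 was at -0.42 ± 0.90 and did not pass. Regenerative epithelium genes had 1 of 12 higher (4 adjusted over the list alone) and endothelial markers 1 of 10 (5 adjusted over the list alone), and both were called as lists (camera adjusted p = 0.00313 and 8.97e-04, and adjusted p = 0.301 and 0.382 with an estimated correlation). The smooth muscle call, downward (0.0193, and adjusted p = 0.624 with an estimated correlation), was lost without normal replicate 2 or LGD replicate 3 (adjusted p up to 0.124). The 15 general epithelial genes had 0 calls by limma and a median of -0.09.

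LGD replicate 1 carried much of several list means in LGD. Without it the mean moved from 2.42 to 1.17 for neutrophils, from 1.26 to 0.76 for STAT3 and epithelial defence, from 0.51 to 0.30 for macrophages, from 0.65 to 0.41 for extracellular matrix and from -1.42 to -0.84 for colonocyte genes, and these calls held.

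LGD had 336 genes higher and 397 lower than normal mucosa. Together these were 733, and all 3 arrays were apart for 30.3% of genes, where chance gives 10%. Leaving out normal replicates 1, 2 or 3 gave 249, 70 or 174 genes. Leaving out LGD replicates 1, 2 or 3 gave 113, 146 or 1787. A fit on only the 6 arrays gave 50. Of 46 genes taken by the naming rule that passed, 5 passed whichever single array was left out (Sptssb, Myl7, Pck1, Slc37a2 and Ppara). LGD replicate 2 had a Gapdh 3 prime to 5 prime log2 ratio of 1.63, against -0.08 to 0.16 in the other arrays.

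**Figure D2:**
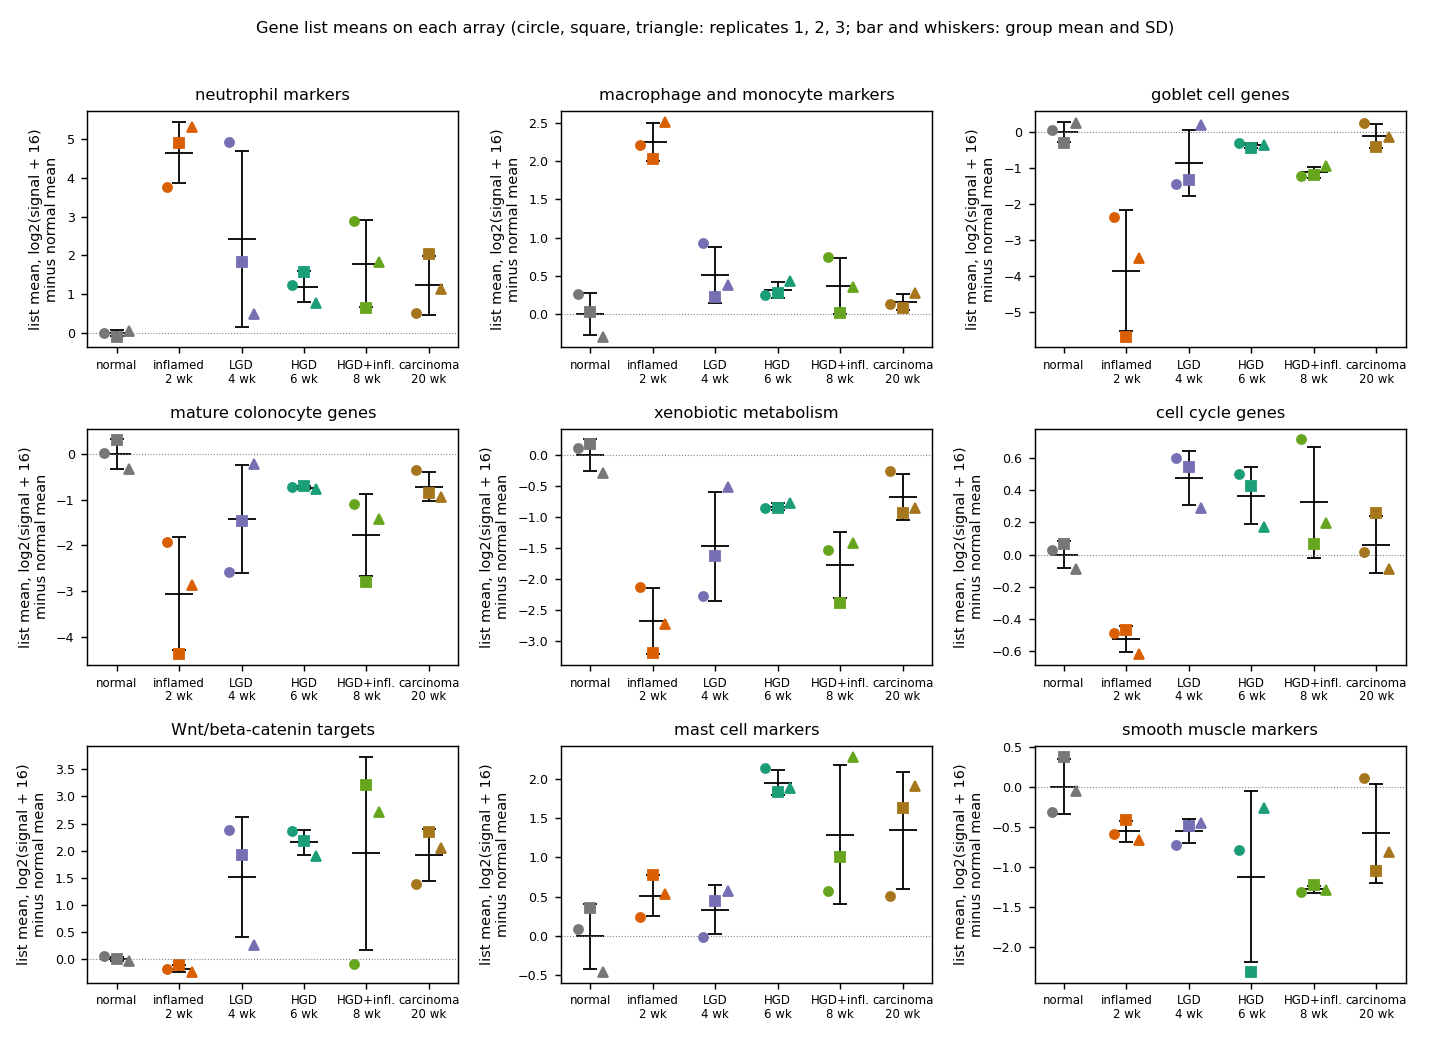
Points give the mean over a gene list on each array, as log2 signal minus the normal mean, for 9 lists in the 6 groups, with bars for the group mean and whiskers for the SD of 3 arrays. Wnt/beta-catenin targets lie at 1.90 to 2.37 in the HGD arrays of 6 weeks, but at 0.26 in LGD replicate 3 and at -0.09 in HGD 8-week replicate 1.

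HGD at 6 weeks against normal mucosa describes high grade lesions sampled between DSS cycles. The metallothionein gene Mt4 rose by 6.59 ± 1.38 (SE, n = 3 per group, adjusted p = 0.0399), the mast cell protease gene Mcpt2 by 5.02 ± 1.08 (adjusted p = 0.0447), Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, by 3.96 ± 0.80, and Sptssb by 3.95 ± 0.45 (adjusted p = 0.00234). Slc37a2 fell by 2.72 ± 0.47, as did the magnesium channel gene Trpm6 (-2.37 ± 0.44) and the fucosyltransferase gene Fut9 (-1.64). The other probe set of Trpm6 was at -1.19. Of 11 mast cell markers, 2 rose, Mcpt2 and the carboxypeptidase gene Cpa3 (2.21 ± 0.50; 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.48e-05, and adjusted p = 0.48 with an estimated correlation). The mean of this list was 1.95 ± 0.16 above normal mucosa (SD, n = 3), against 0.34 ± 0.31 in LGD.

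Wnt/beta-catenin targets had 0 of 21 calls over all genes by limma and 15 higher adjusted over the list alone, with a median of 1.61 (camera adjusted p = 1.56e-10, and adjusted p = 0.482 with an estimated correlation). With only the 6 arrays fitted, 19 of the 21 were higher. The Wnt inhibitor gene Wif1 had a log2 change of 5.41 ± 1.25 (adjusted p = 0.054), Axin2 of 2.08 ± 0.70 (adjusted p = 0.131) and Myc of 0.65 ± 0.19 (adjusted p = 0.102). Of 14 proteases and inhibitors, 2 rose, the plasminogen activator gene Plat by 3.01 ± 0.62 and Mmp12 by 2.65 ± 0.56 (6 adjusted over the list alone, camera adjusted p = 3.57e-05, and adjusted p = 0.482 with an estimated correlation). The other probe set of Plat had a log2 change of 0.39, and that of Sptssb 1.55. Cell cycle genes had 0 of 27 calls by limma and a median of 0.37 (1 adjusted over the list alone, camera adjusted p = 3.67e-06, and adjusted p = 0.502 with an estimated correlation). In a fit of only the 6 arrays 8 of the 27 were higher, and Mki67 was at -0.11. Smooth muscle markers had 0 calls by limma but 12 of 12 lower adjusted over the list alone, with a median of -1.13 (camera adjusted p = 1.28e-06, and adjusted p = 0.499 with an estimated correlation). Fitted on only the 6 arrays, 0 of these 12 were called. Without HGD replicate 2 the mean of the list moved from -1.12 to -0.53 (adjusted p = 1.84e-04). Of 10 enteric neuron and glia markers, 2 fell, the neurofilament genes Nefl (-1.21 ± 0.25) and Nefm at -1.04 ± 0.23 (4 adjusted over the list alone, camera adjusted p = 4.27e-04, and adjusted p = 0.48 with an estimated correlation). Xenobiotic metabolism had 1 of 15 lower, the retinaldehyde dehydrogenase gene Aldh1a1 at -1.39 ± 0.27 (1 adjusted over the list alone, camera adjusted p = 3.3e-04, and adjusted p = 0.502 with an estimated correlation). Fatty acid oxidation had 1 of 15 lower (2 adjusted over the list alone, camera adjusted p = 7.62e-04, and adjusted p = 0.48 with an estimated correlation). Enteroendocrine genes had 0 of 9 calls by limma, 1 lower adjusted over the list alone and 7 with only the 6 arrays fitted (camera adjusted p = 0.00638, and adjusted p = 0.502 with an estimated correlation). The colonocyte call, with 1 of 21 lower (0.0147, and adjusted p = 0.65 with an estimated correlation), was lost without normal replicate 2 (adjusted p = 0.0745). Goblet cell genes had 0 of 15 calls by limma (camera adjusted p = 0.135), with Muc2 at -0.22, and the 15 general epithelial genes had a median of -0.07.

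Some immune lists were called at 6 weeks and held whichever single array was left out: cytokines and chemokines (1 of 18 higher, 3 adjusted over the list alone) and STAT3 and epithelial defence (0 of 14 by limma, 4 adjusted over the list alone and 8 with only the 6 arrays fitted). Their camera adjusted p was 9.02e-04 and 0.00158, and the adjusted p was 0.502 for both with an estimated correlation. Calls for neutrophils (0.0268), NF-kB targets (0.0316) and macrophages (0.00482) were lost without single arrays, with an adjusted p of up to 0.0562, 0.0798 and 0.052. These arrays were normal replicate 1 and HGD replicate 2 for neutrophils, normal replicates 2 and 3 and HGD replicates 2 and 3 for NF-kB targets, and normal replicate 3 and HGD replicate 3 for macrophages. With an estimated correlation the adjusted p was 0.65, 0.65 and 0.502.

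HGD at 6 weeks had 80 genes higher and 67 lower than normal mucosa, 147 together. Leaving out normal replicates 1, 2 or 3 gave 20, 8 or 26 genes. Leaving out HGD replicates 1, 2 or 3 gave 8, 6 or 127. A fit on only the 6 arrays gave 1633. Such fits gave 50 for LGD and 761 for HGD at 8 weeks. The model on all arrays takes the same spread for a gene in every group. The median SD over genes was 0.133 in HGD at 6 weeks, 0.190 in LGD and 0.206 in HGD at 8 weeks. The counts on all arrays therefore need not rank these stages by how much they changed. Of 23 genes taken by the naming rule that passed, 1 passed whichever single array was left out (Sptssb).

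HGD with active inflammation at 8 weeks against normal mucosa adds a recent DSS cycle. Cxcl5 rose by 5.23 ± 1.05 (SE, n = 3 per group, adjusted p = 0.0106), S100a8 by 5.70 ± 1.30 (adjusted p = 0.0175), Saa3 by 4.44 ± 1.07, Lcn2 by 4.10 ± 1.07 and Sptssb by 3.95 ± 0.45. The other probe set of Sptssb had a log2 change of 1.54. Sult1a1 fell by 3.70 ± 0.62, as did Pck1 (-3.46 ± 0.53), the ceramidase gene Acer1 (-3.24 ± 0.47) and the urea cycle gene Otc at -3.17 ± 0.44 (adjusted p = 0.00228). Mptx1 fell by 5.12 ± 1.53 (adjusted p = 0.0458).

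Of 21 Wnt/beta-catenin targets, 5 rose in this group: Wif1 by 4.22 ± 1.25, Apcdd1 by 3.94 ± 1.10, Sp5 by 3.01 ± 0.91, Cd44 by 1.11 ± 0.28 and Myc by 0.65 ± 0.19 (16 adjusted over the list alone, camera adjusted p = 8.3e-07, and adjusted p = 0.432 with an estimated correlation). The mean of the list was -0.09 in replicate 1 against 3.21 and 2.72 in replicates 2 and 3, so that it was 1.95 over the group and 2.97 without replicate 1. With only the 6 arrays fitted, 2 of 21 were higher. The 4 other probe sets of Apcdd1 ran from 1.06 to 3.90. Axin2 was at 1.83 ± 0.70 (adjusted p = 0.0939) and Mki67 at -0.13. Proteases and inhibitors had 4 of 14 higher, Mmp10 by 3.62 ± 0.76 (10 adjusted over the list alone, camera adjusted p = 6.34e-06, and adjusted p = 0.432 with an estimated correlation). Of 15 xenobiotic metabolism genes, 9 fell (11 adjusted over the list alone), including the drug transporter gene Abcb1a with a log2 change of -2.52 (camera adjusted p = 1.74e-08, and adjusted p = 0.432 with an estimated correlation). Of 21 colonocyte genes, 3 fell, among them the monocarboxylate transporter gene Slc16a1 at -1.63 ± 0.32 (9 adjusted over the list alone, camera adjusted p = 9.05e-06, and adjusted p = 0.432 with an estimated correlation). Of 15 goblet cell genes, 4 fell, including Klk1 (-2.53 ± 0.71) and Atoh1 at -1.82 ± 0.35 (5 adjusted over the list alone, camera adjusted p = 0.0015, and adjusted p = 0.491 with an estimated correlation). The 3 other probe sets of Klk1 ran from -2.55 to 0.12, and 2 of them fell. Of 12 smooth muscle markers, 5 fell, such as Pgm5 at -1.56 ± 0.47 (12 adjusted over the list alone, camera adjusted p = 5.68e-06, and adjusted p = 0.432 with an estimated correlation). Of 10 neuron and glia markers, 4 fell, Nefl at -1.28 ± 0.25 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00269, and adjusted p = 0.432 with an estimated correlation). Fatty acid oxidation had 5 of 15 lower (7 adjusted over the list alone, camera adjusted p = 1.02e-05) and enteroendocrine genes 1 of 9 (5 adjusted over the list alone, 0.00146), and both had an adjusted p of 0.432 with an estimated correlation. Without HGD 8-week replicate 2 the enteroendocrine mean moved from -1.49 to -0.86. The 15 general epithelial genes had 0 calls by limma and a median of -0.35.

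Several lists at 8 weeks, most of them immune, rested on single arrays. Neutrophil markers had 2 of 14 higher (2 adjusted over the list alone, camera adjusted p = 0.00597, and adjusted p = 0.624 with an estimated correlation). That call was lost without HGD 8-week replicate 1 (adjusted p = 0.194). Cytokines and chemokines (0.0012, then 0.104 without that array), STAT3 and epithelial defence (0.00417, then 0.129), macrophages and monocytes (0.0102, then 0.276), regenerative epithelium (0.00865, then 0.0605) and the cell cycle (0.00105, then 0.443) were lost in the same way, and the macrophage call also without normal replicate 3. For these 5 lists the adjusted p was 0.432 to 0.538 with an estimated correlation. Of their members 1 of 18 was higher in the cytokine list (1 adjusted over the list alone), 3 of 14 in the STAT3 list (7) and 3 of 12 in the regenerative list (4). In the macrophage list 3 of 16 were higher and 1 lower (7 and 1), and in the cell cycle list 1 of 27 was higher and 1 lower (1 and 1). Mast cell markers had 1 of 11 higher, the IgE receptor gene Ms4a2 by 2.11 ± 0.64, and 1 lower, the stem cell factor receptor gene Kit at -1.05 ± 0.21 (4 and 1 adjusted over the list alone, camera adjusted p = 0.00674, and adjusted p = 0.432 with an estimated correlation). The mast cell call was lost without replicate 3 (adjusted p = 0.11). Means of the main immune lists against normal mucosa overlapped those at 6 weeks (SD, n = 3). At 8 and 6 weeks they were 1.79 ± 1.11 and 1.20 ± 0.40 for neutrophils and 1.39 ± 0.83 and 1.18 ± 0.43 for cytokines. For STAT3 and epithelial defence they were 1.50 ± 1.10 and 1.47 ± 0.18, and for macrophages 0.37 ± 0.37 and 0.32 ± 0.10.

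HGD at 8 weeks had 623 genes higher and 828 lower than normal mucosa. Together these were 1451, and all 3 arrays were apart for 33.5% of genes, where chance gives 10%. Leaving out normal replicates 1, 2 or 3 gave 607, 333 or 597 genes. Leaving out HGD 8-week replicates 1, 2 or 3 gave 2204, 553 or 700. A fit on only the 6 arrays gave 761. Of 72 genes taken by the naming rule that passed, 22 passed whichever single array was left out, among them Cxcl5, Sptssb, Sult1a1, Pck1, Otc, Slc37a2, Atoh1 and Ppara.

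Carcinoma at 20 weeks against normal mucosa describes the end of the model. Sptssb rose by 3.83 ± 0.45 (SE, n = 3 per group, adjusted p = 0.00228), the transcription factor gene Sox17 by 2.88 ± 0.34 (adjusted p = 0.00228), Tnfrsf11b by 3.94 ± 0.80 (adjusted p = 0.039), Plat by 3.14 ± 0.62 and Wfdc18 by 2.84 ± 0.54. The other probe sets of Plat, Sptssb and Sox17 had log2 changes of 0.75, 1.77 and 1.19. Slc37a2 fell by 2.50 ± 0.47 (adjusted p = 0.0303), as did Trpm6 (-2.24 ± 0.44), Fut9 (-1.73 ± 0.28), Aldh1a1 (-1.35 ± 0.27) and Ppara at -0.63 ± 0.09 (adjusted p = 0.00491). The other probe set of Trpm6 was at -1.06. Wnt/beta-catenin targets had 0 of 21 calls over all genes by limma and 14 higher adjusted over the list alone, with a median of 1.44 (camera adjusted p = 1.36e-10, and adjusted p = 0.341 with an estimated correlation). With only the 6 arrays fitted, 14 of the 21 were higher. Axin2 was at 1.85 ± 0.70 (adjusted p = 0.182), Cd44 at 1.21 ± 0.28 (adjusted p = 0.0519) and Myc at 0.59 (adjusted p = 0.134).

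Proteases and inhibitors had 1 of 14 higher in carcinoma, Plat (7 adjusted over the list alone, camera adjusted p = 3.78e-07, and adjusted p = 0.341 with an estimated correlation). Mast cell markers had 0 of 11 calls by limma, over all genes and adjusted over the list alone, with a median of 1.22 and Mcpt2 at 3.25 ± 1.08 (camera adjusted p = 3.21e-04, and adjusted p = 0.341 with an estimated correlation). In a fit of only the 6 arrays 1 of these was higher. Fatty acid oxidation had 1 of 15 lower, Ppara (7 adjusted over the list alone, camera adjusted p = 7.94e-05, and adjusted p = 0.341 with an estimated correlation). Enteric neuron and glia markers had 0 of 10 calls by limma and 5 lower adjusted over the list alone (camera adjusted p = 0.00422, and adjusted p = 0.341 with an estimated correlation). MAPK targets had 1 of 12 higher, the receptor kinase gene Epha2 by 0.71 ± 0.15 (4 adjusted over the list alone, camera adjusted p = 0.0345, and adjusted p = 0.341 with an estimated correlation). The p53 response had 0 of 15 calls by limma, over all genes, adjusted over the list alone and with only the 6 arrays fitted (camera adjusted p = 0.0345, and adjusted p = 0.341 with an estimated correlation). The p53 call was lost without normal replicate 3 or carcinoma replicates 2 or 3 (adjusted p up to 0.0986). The MAPK call was lost without normal replicate 3 or carcinoma replicate 3 (adjusted p up to 0.0651). Xenobiotic metabolism was lower as a list (1 of 15 lower, 3 adjusted over the list alone and 4 with only the 6 arrays fitted, camera adjusted p = 0.00554, and adjusted p = 0.671 with an estimated correlation). Calls for smooth muscle, downward (0.019), and squamous epithelium, upward (0.0345), were lost without single arrays. These were normal replicate 2 and carcinoma replicates 2 and 3 for smooth muscle (adjusted p up to 0.169) and carcinoma replicate 2 for squamous epithelium (adjusted p = 0.29), and with an estimated correlation the adjusted p was 0.72 and 0.593. Cell cycle genes (median -0.02, camera adjusted p = 0.362), goblet cell genes (median -0.10, 0.718) and colonocyte genes (0.0647) did not pass, and Mki67 was at -0.16. The 15 general epithelial genes had a median of -0.15.

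Immune lists were also called in carcinoma. Neutrophil markers (0 of 14 by limma, 0 adjusted over the list alone and 3 with only the 6 arrays fitted), cytokines and chemokines (0 of 18, 1 and 3) and STAT3 and epithelial defence (0 of 14, 3 and 3, with 1 lower) were higher as lists whichever single array was left out. Their camera adjusted p was 0.00554, 0.00388 and 0.0033, and the adjusted p was 0.72, 0.671 and 0.575 with an estimated correlation. The macrophage call (0.0416, and adjusted p = 0.72 with an estimated correlation) was lost without normal replicate 3 or carcinoma replicates 1 or 3 (adjusted p up to 0.35).

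Carcinoma had 42 genes higher and 74 lower than normal mucosa. Together these were 116, and all 3 arrays were apart for 31.5% of genes, where chance gives 10%. Leaving out normal replicates 1, 2 or 3 gave 8, 9 or 49 genes. Leaving out carcinoma replicates 1, 2 or 3 gave 287, 11 or 22. A fit on only the 6 arrays gave 529. Of 18 genes taken by the naming rule that passed, 3 passed whichever single array was left out (Sptssb, Sox17 and Ppara).

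**Figure D3:**
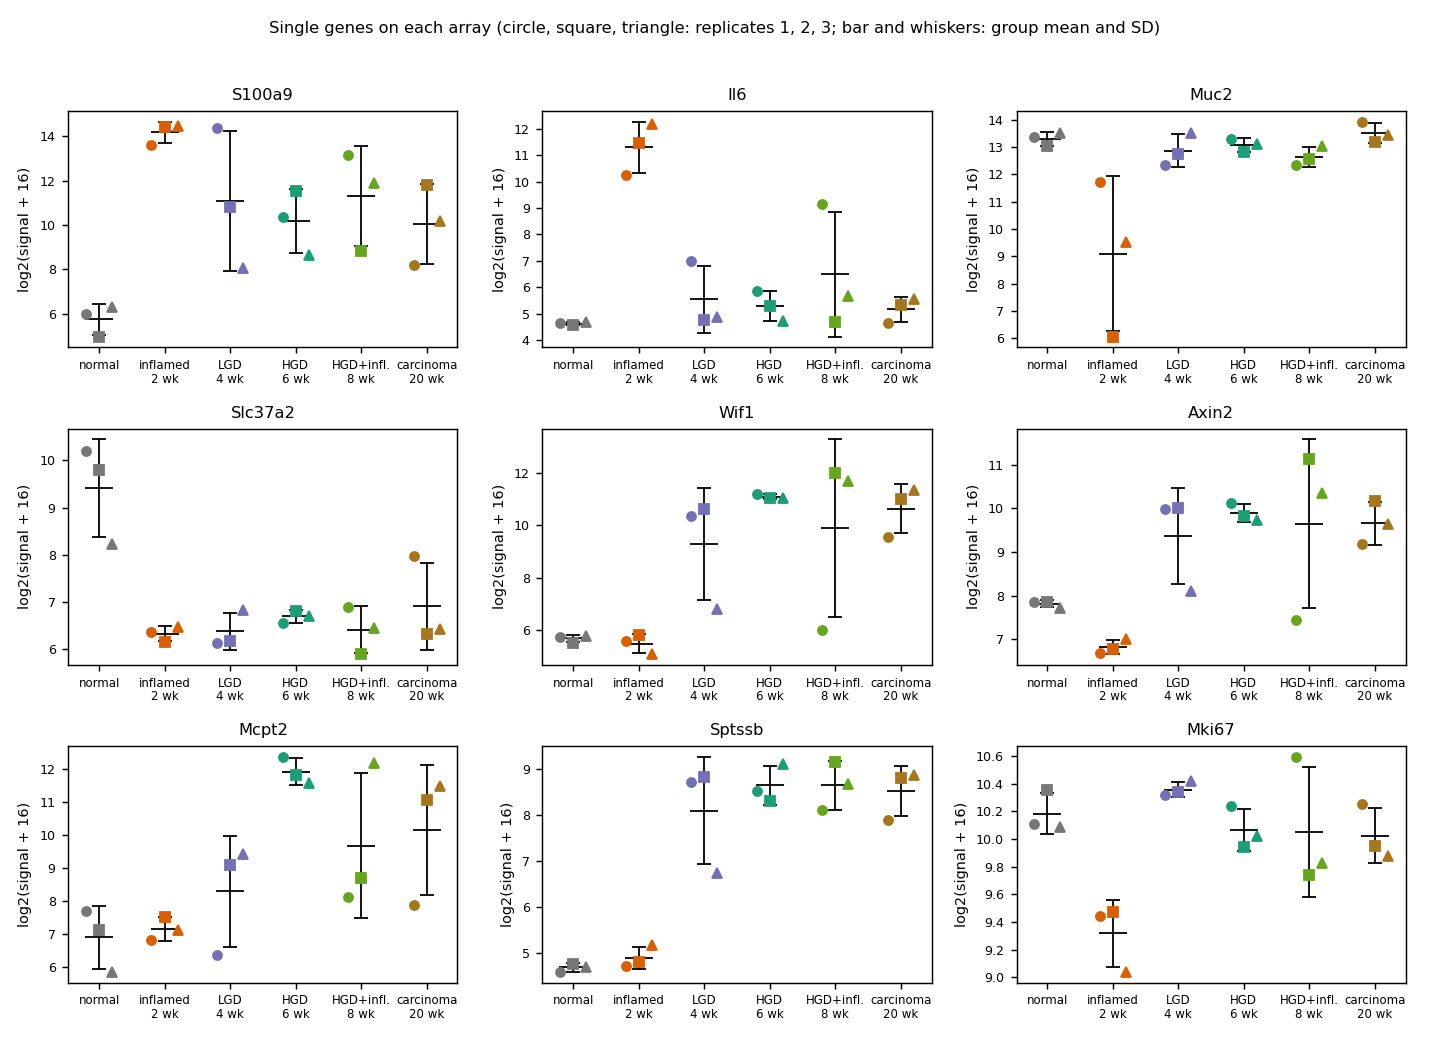
Points give log2(signal + 16) of 9 genes, picked from the named genes after their values were seen, on each of the 18 arrays in the 6 groups, with bars for the group mean and whiskers for the SD of 3 arrays. S100a9 rises from a mean of 5.75 in normal to 14.18 in inflamed mucosa, and Wif1 stands at 6.82 in LGD replicate 3 and 5.99 in HGD 8-week replicate 1 but at 9.56 or more in the other 10 lesion arrays.

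The step from inflamed mucosa to LGD, tested directly, showed epithelial and proliferation genes higher and inflammatory genes lower. Ang4 was higher by 7.03 ± 0.82 (SE, n = 3 per group, adjusted p = 2.81e-05), Reg4 by 5.65 ± 0.68, the lectin gene Itln1 by 4.83 ± 0.85 and Muc2 by 3.78 ± 0.90 (adjusted p = 0.00477). Il6 fell by 5.75 ± 0.90 (adjusted p = 2.45e-04), as did Marco (-5.31 ± 0.19), the monocyte chemokine gene Ccl2 (-4.70 ± 0.48) and Il11 (-4.57 ± 0.72). The other probe set of Marco was at -2.75. Of 27 cell cycle genes, 20 rose (22 adjusted over the list alone), the topoisomerase gene Top2a by 1.58 ± 0.17 and Mki67 by 1.04 ± 0.19 (camera adjusted p = 3.65e-10, and adjusted p = 0.449 with an estimated correlation). The other probe set of Top2a had a log2 change of 0.63. Of 21 Wnt/beta-catenin targets, 10 rose (10 adjusted over the list alone), with Axin2 by 2.54 ± 0.70 (adjusted p = 0.0109), Rnf43, which removes Wnt receptors, by 2.87 ± 0.58 and Myc by 0.59 ± 0.19 (camera adjusted p = 0.00101, and adjusted p = 0.563 with an estimated correlation). Goblet cell genes rose in 13 of 15 cases (13 adjusted over the list alone, camera adjusted p = 6.06e-06, and adjusted p = 0.449 with an estimated correlation). Beside them, 15 of 15 general epithelial genes rose with a median of 3.02. Of 16 macrophage markers, 13 fell (14 adjusted over the list alone, camera adjusted p = 1e-08, and adjusted p = 0.322 with an estimated correlation). Of 18 cytokines and chemokines, 11 fell (11 adjusted over the list alone, camera adjusted p = 1.43e-04, and adjusted p = 0.563 with an estimated correlation). All 10 neuron and glia markers fell, such as Uchl1 at -2.80 ± 0.33 (10 adjusted over the list alone, camera adjusted p = 1.8e-07, and adjusted p = 0.203 with an estimated correlation). Also lower as lists, whichever single array was left out, were endothelial markers (7 of 10, camera adjusted p = 7.34e-05), NF-kB targets (9 of 14, 3.33e-04), extracellular matrix (9 of 17, 3.33e-04), proteases (10 of 14, with 1 higher, 9.12e-04), neutrophil markers (5 of 14, 0.00209) and eicosanoid genes (6 of 13, with 1 higher, 0.0177). For these 6 lists the adjusted p was 0.322 to 0.563 with an estimated correlation. Without LGD replicate 3 the mean moved from -2.22 to -1.27 for neutrophils, from -0.82 to -0.54 for extracellular matrix and from -1.62 to -1.05 for proteases, and without LGD replicate 1 it was -3.47 for neutrophils. Calls for STAT3 and epithelial defence, T cells, immediate early genes and enteroendocrine genes, all downward, and for colonocyte genes and xenobiotic metabolism, both upward, were each lost without at least 1 single array and are not given singly. Between these stages 2483 genes were higher and 2195 lower, 4678 together. All 3 arrays were apart for 45.9% of genes, where chance gives 10%. Of 101 genes taken by the naming rule that passed, 69 passed whichever single array was left out.

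The 4 later comparisons between stages gave 0 genes by limma. At an unadjusted p under 0.05 there were 900 genes for HGD at 6 weeks against LGD, 423 for HGD at 8 against 6 weeks, 1422 for carcinoma against HGD at 8 weeks and 580 for carcinoma against HGD at 6 weeks, where chance gives 643.9. Fits on only the 6 arrays gave 0, 1, 0 and 0. All 3 arrays were apart for 12.3%, 10.2%, 16.3% and 14.3% of genes, where chance gives 10%. HGD at 6 weeks against LGD gave 55 genes without LGD replicate 3 and 1 without HGD 6-week replicate 3. Carcinoma against HGD at 8 weeks gave 2, 1 or 2 genes without HGD 8-week replicate 1, HGD 8-week replicate 3 or carcinoma replicate 1, and carcinoma against HGD at 6 weeks gave 1 without HGD 6-week replicate 3.

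Gene lists gave calls between these stages where single genes did not. From LGD to HGD at 6 weeks, extracellular matrix and fibroblast genes had a median of -0.93 with 12 of 17 lower adjusted over the list alone (camera adjusted p = 1.48e-17, and adjusted p = 0.0914 with an estimated correlation). Col4a1 was at -1.16 ± 0.24 (SE, n = 3 per group, limma adjusted p = 0.35). Mast cell markers had a median of 1.34 with 7 of 11 higher adjusted over the list alone (camera adjusted p = 1.22e-10, and adjusted p = 0.0772 with an estimated correlation). Cpa3 was at 2.04 ± 0.50 (limma adjusted p = 0.408). Endothelial markers had a median of -0.53 with 7 of 10 lower adjusted over the list alone (camera adjusted p = 1.83e-11, and adjusted p = 0.0609 with an estimated correlation). From 6 to 8 weeks, xenobiotic metabolism (median -0.85, camera adjusted p = 5.35e-11), colonocyte genes (-0.92, 7.96e-07) and goblet cell genes (-0.62, 1.24e-04) were lower as lists. Their adjusted p was 0.384, 0.572 and 0.572 with an estimated correlation. The same 3 lists were higher in carcinoma than in HGD at 8 weeks, with medians of 0.91, 0.84 and 0.88. Both steps share the HGD 8-week arrays, and without replicate 2 of that group the colonocyte mean moved from -1.04 to -0.53 for the first step and from 1.06 to 0.55 for the second. Their camera adjusted p was 4.34e-09, 8.57e-06 and 1.33e-05, and the adjusted p was 0.483, 0.614 and 0.614 with an estimated correlation. Between carcinoma and HGD at 6 weeks, p53 response genes were higher with a median of 0.11, 2 of 15 adjusted over the list alone (camera adjusted p = 2.09e-04, and adjusted p = 0.0407 with an estimated correlation). The cyclin gene Ccng1 was at 0.44 ± 0.11 and did not pass by itself. The p53 call was the 1 of 135 across all comparisons that held with an estimated correlation. List p-values were adjusted within each comparison and not over the 10 comparisons, so a single such call may arise by chance. Against HGD at 8 weeks the p53 list was also higher in carcinoma (camera adjusted p = 0.0214, and adjusted p = 0.483 with an estimated correlation), and that call was lost without HGD 8-week replicate 1 or carcinoma replicate 2 (adjusted p up to 0.131). Cell cycle genes were lower as a list in carcinoma than in HGD at 6 weeks (median -0.34, camera adjusted p = 2.83e-08, and adjusted p = 0.697 with an estimated correlation). Against HGD at 8 weeks the cell cycle call (camera adjusted p = 3.25e-04, and adjusted p = 0.614 with an estimated correlation) was lost without HGD 8-week replicate 1 (adjusted p = 0.821).

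Of the further list calls between these stages, 4 held whichever single array was left out. Fatty acid oxidation was higher in HGD at 6 weeks than in LGD (median 0.24, camera adjusted p = 3.63e-05, and adjusted p = 0.152 with an estimated correlation). It was lower in HGD at 8 than at 6 weeks (median -0.21, camera adjusted p = 1.25e-04, and adjusted p = 0.384 with an estimated correlation), where the mean moved from -0.17 to -0.10 without HGD 8-week replicate 1. Smooth muscle markers were higher in carcinoma than in HGD at 8 weeks (median 0.72, camera adjusted p = 2.37e-05, and adjusted p = 0.614 with an estimated correlation), and the mean moved from 0.70 to 0.35 without carcinoma replicate 1. Endothelial markers were higher in carcinoma than in HGD at 6 weeks (median 0.20, camera adjusted p = 7.98e-04, and adjusted p = 0.697 with an estimated correlation), and the mean moved from 0.23 to 0.14 without HGD 6-week replicate 2. The other list calls between these stages were each lost without at least 1 single array and are not given singly.

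Across all 5 stages, 36 genes changed in the same direction against normal mucosa, 10 higher and 26 lower. Independent lists would give 2.6e-04. Slc37a2, Ppara and Trpm6 are among the 26. Slc37a2 fell by 3.08 ± 0.47 in inflamed mucosa and fell by 2.50 ± 0.47 in carcinoma. Ifitm3 and Ifitm1, interferon-induced membrane protein genes named after their values were seen, are among the 10. Ifitm3 rose by 1.90 ± 0.24 in inflamed mucosa and 1.21 ± 0.24 in carcinoma. The count was 6, 4 or 11 without normal replicates 1, 2 or 3, and 17, 20, 3, 5, 16, 6 or 7 without inflamed replicate 3, LGD replicate 2, HGD 6-week replicates 1 or 2, HGD 8-week replicate 3 or carcinoma replicates 2 or 3. It was 101, 82 or 74 without LGD replicate 3, HGD 8-week replicate 1 or carcinoma replicate 1. Because all stages share the 3 control arrays, the overlap between stages can be raised by them. HGD at 6 and 8 weeks shared 69 higher and 65 lower genes, where independent lists would share 3.87 and 4.31. Inflamed mucosa and LGD shared 223 and 336, where 75.7 and 96.5 are expected.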

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

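The comparisons in this part were planned, except that the Gapdh ratio of a single array was singled out after its value was seen. Genes and lists that moved in opposite directions against normal mucosa in adjacent stages, and that differed when these stages were compared directly, are given first. In all, 26 genes changed in opposite directions against normal mucosa in inflamed mucosa and LGD and also differed between these stages by limma. Of these, 6 were higher in inflamed mucosa and lower in LGD, such as the peptide hormone gene Grp (1.42, then -1.17 on the log2 scale) and the neuronal RNA-binding protein gene Elavl4 (1.07, then -0.59). The other 20 were lower in inflamed mucosa and higher in LGD, among them the proliferation genes Top2a (-0.97, then 0.61), Plk1 (-0.79, then 0.63) and Mcm7 (-0.49, then 0.65) and the sterol synthesis genes Idi1 (-0.77, then 0.87) and Fdft1 (-0.83, then 0.69). These genes, Elavl4 and Top2a aside, were named after their values were seen. The 15 general epithelial genes had a median log2 change of -3.03 in inflamed mucosa and -0.09 in LGD against normal mucosa. From inflamed mucosa to LGD it was 3.02. A changed share of epithelial cells may thus account for part of the changes in inflamed mucosa, here and in the cell cycle and neuron lists below. This was not tested.

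The cell cycle list lay at a mean of -0.53 ± 0.08 in inflamed mucosa and 0.48 ± 0.17 in LGD against normal mucosa (SD, n = 3), a difference of 1.00. Extracellular matrix and fibroblast genes lay at 0.65 ± 0.53 in LGD and -0.26 ± 0.23 in HGD at 6 weeks, a difference of -0.91. The call for HGD at 6 weeks against normal mucosa (camera adjusted p = 0.0297, and adjusted p = 0.65 with an estimated correlation) was lost without normal replicates 2 or 3 or HGD 6-week replicate 2 (adjusted p up to 0.194). Enteric neuron and glia markers lay at 1.22 ± 0.22 in inflamed mucosa and -0.39 ± 0.07 in LGD, a difference of -1.61. The call for LGD against normal mucosa (camera adjusted p = 0.0219, and adjusted p = 0.382 with an estimated correlation) was lost without normal replicate 2 or LGD replicate 3 (adjusted p up to 0.0762). Camera called each of these 3 differences, and none was called with an estimated correlation (adjusted p = 0.449, 0.0914 and 0.203).

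The control probe sets of Gapdh gave a 3 prime to 5 prime log2 ratio of 1.63 in LGD replicate 2, above the 3 normal arrays (mean -0.01 ± 0.09, SD), and its beta-actin ratio was 1.51. Over the 6 groups the Kruskal-Wallis permutation p was 0.502 for the Gapdh ratio, 0.232 for the beta-actin ratio and 0.0105 for the 18S control signal, which was lowest in inflamed mucosa. Probe sets that the annotation pairs with no gene or with several genes also carried signal: of 3383 tested, 1034 differed from normal in inflamed mucosa, 85 in LGD, 38 in HGD at 6 weeks, 377 in HGD at 8 weeks and 49 in carcinoma.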

How the results depend on the processing

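Most alternatives here were planned; leaving out LGD replicate 3 and HGD 8-week replicate 1 together, and the method of array weights, were chosen after seeing the data. For the counts of genes, the pseudocounts of 1 and 64, both other filters, quantile normalization, median centring, the mean of a gene's probe sets and no intensity trend kept every count within 1.5 times. Of 370 named gene calls, 331 or more passed under those 8 alternatives (352 of 355 measured under the upper-half filter), 370 with array weights, 316 with the replicate block, 270 in fits on 6 arrays and 1527 of 2220 when single arrays were left out, and 0 reversed. Of 135 gene list calls, 132 to 135 held under those 8 alternatives, 122 with array weights, 133 in fits on 6 arrays, 111 without both arrays, 135 without shared members and 715 of 810 when single arrays were left out. For the list tests the preset correlation decides: 1 call held with an estimated correlation, and 129 to 160 lists were called when single arrays were left out. Dim genes are limited by signal over background, since the table median is 56.5 and the pseudocount 16.

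A 2-fold minimum, which can only lower a count, left 2463 genes for inflamed mucosa, 202 for LGD, 68 and 494 for HGD at 6 and 8 weeks, 46 for carcinoma, 1719 for LGD against inflamed mucosa and 14 for all 5 stages. Array weights gave 2279 for LGD, 2308 and 4749 for HGD at 6 and 8 weeks, 2690 for carcinoma, 10 for HGD at 8 against 6 weeks, 112 and 8 for carcinoma against HGD at 8 and 6 weeks, 8842 for the F test and 636 for all 5 stages. Fits on only the 6 arrays gave 50 for LGD, 1633 and 761 for HGD at 6 and 8 weeks, 529 for carcinoma and 1 for HGD at 8 against 6 weeks. Without LGD replicate 3 and HGD 8-week replicate 1 the counts were 2378 for LGD, 749 and 2547 for HGD at 6 and 8 weeks, 802 for carcinoma, 82 for HGD at 6 weeks against LGD, 27 for carcinoma against HGD at 8 weeks and 228 for all 5 stages. Leaving out single arrays gave 70 to 1787 for LGD, 6 to 127 and 333 to 2204 for HGD at 6 and 8 weeks, 8 to 287 for carcinoma, 0 to 55 for HGD at 6 weeks against LGD, 0 to 2 and 0 to 1 for carcinoma against HGD at 8 and 6 weeks, 4322 to 6941 for the F test and 3 to 101 for all 5 stages. Apart from the 2-fold minimum, the cause was not tested. The median SD over genes differed between groups, from 0.131 in normal mucosa to 0.206 in HGD at 8 weeks. How far this moved the counts was not tested.

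With the replicate number as a block, 31 genes passed for HGD at 6 weeks, 44 for carcinoma and 12 for all 5 stages. Arrays with the same number did not resemble each other (median r = -0.00134 over genes, 11 of 45 pairs over 0.1), so the number was not used to pair arrays.

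List tests that turned direction were all between stages, and the cause was not tested. Values are list means, with the range when single arrays were left out. For HGD at 6 weeks against LGD, Wnt/beta-catenin targets moved from 0.64 to 0.00928 without LGD replicate 3, alone or with the other array (range 0.00928 to 1.07), with the test of the list against other genes turning downward. Proteases moved from -0.51 to 0.0883 without LGD replicate 1 (range -1.08 to 0.0883) and smooth muscle markers from -0.57 to 0.0294 without HGD 6-week replicate 2 (range -0.99 to 0.0294). For HGD at 8 against 6 weeks, without HGD 8-week replicate 2, interferon genes moved from -0.46 to 0.0234 (range -0.78 to 0.0234) and hypoxia genes from -0.20 to 0.00554 (range -0.33 to 0.00554). Mast cell markers moved from -0.66 to 0.126 with array weights.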

Other observations

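The tests of explanations in this part were chosen after the results were seen, except that of epithelial loss and the counts over other splits of the arrays. Genes of the circadian clock are not on the lists above. Of 8 clock output genes, 1, 2, 0, 3 and 0 passed against normal mucosa in inflamed mucosa, LGD, HGD at 6 weeks, HGD at 8 weeks and carcinoma, each lower. Per3, a period gene, fell by 1.40 ± 0.29 in inflamed mucosa (SE, n = 3 per group, limma adjusted p = 0.00106). It fell by 1.50 ± 0.29 in LGD (adjusted p = 0.0139) and fell by 1.09 ± 0.29 in HGD at 8 weeks (adjusted p = 0.0307). Hlf, a clock-controlled transcription factor gene, fell by 1.29 ± 0.29 in LGD and fell by 1.24 ± 0.29 in HGD at 8 weeks. Members of the output set did not all move one way. Nr1d1 lay above normal mucosa in every stage, from 0.30 in inflamed mucosa to 1.21 in carcinoma. In HGD at 6 weeks Dbp and Ciart were at 1.32 and 0.59, but Hlf and Per2 at -0.82 and -0.62. In carcinoma Dbp and Ciart were at 1.11 and 0.69, but Hlf and Per2 at -0.79 and -0.82. None of these values passed, and means of the set hide such splits. Of 4 genes that peak in the opposite phase, 3 passed in inflamed mucosa, 0 in LGD and carcinoma and 1 in HGD at 6 and at 8 weeks. The core activator gene Arntl fell by 1.41 ± 0.28 in HGD at 6 weeks (adjusted p = 0.0359) and fell by 1.08 ± 0.28 at 8 weeks (adjusted p = 0.0293). In inflamed mucosa Npas2 fell by 1.32 ± 0.25 (adjusted p = 6.43e-04) and Clock fell by 0.74 ± 0.12 (adjusted p = 2.2e-04), while Nfil3, which is also induced by cytokines, rose by 3.15 ± 0.43. These genes were named after their values were seen.

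Output minus antiphase genes averaged -0.69 ± 0.13 in inflamed mucosa, -0.57 ± 0.48 in LGD, 0.72 ± 0.55 in HGD at 6 weeks, -0.18 ± 0.31 at 8 weeks and 0.74 ± 0.70 in carcinoma (SD, n = 3). In inflamed mucosa the sign rests on Nfil3. Without it the averages were 0.31 ± 0.09, -0.30 ± 0.35, 0.87 ± 0.47, 0.13 ± 0.16 and 0.86 ± 0.67, so the sign turned in inflamed mucosa and in HGD at 8 weeks, and the arrays of 0 stages lay clear of normal mucosa. Collection at another time of day may account for part of this shift: the difference varied over the 6 groups (Kruskal-Wallis permutation p = 0.00453, and 0.0213 without Nfil3). A loss of cell types that carry all clock genes would move both sets one way. The medians of output and antiphase genes were both below 0 in inflamed mucosa (-0.50 and -0.61), LGD (-0.61 and -0.17) and HGD at 8 weeks (-0.48 and -0.54), but opposite in HGD at 6 weeks (0.17 and -0.41) and carcinoma (0.19 and -0.48). In 0 stages were they opposite with arrays clear of normal mucosa in the difference, so such a loss is not excluded. Both tests were revised after their first results were seen, the labels give no collection hour, and the 2 explanations cannot be told apart.

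The signal of Wnt/beta-catenin targets was near that of normal mucosa in 2 of 12 lesion arrays, LGD replicate 3 (0.26) and HGD 8-week replicate 1 (-0.09). Degraded RNA is argued against by their Gapdh ratios, of which the higher was 0.0622, and exchange with a normal or inflamed array by the highest Wnt mean of those 6 arrays, 0.0448. Dilution of a lesion by other mucosa would keep a like share of every lesion signal. The 15 Wnt genes kept a median of 2.37% and -2.29% of their increase in HGD at 6 weeks, but the 2 arrays were singled out for this low signal. The 38 other genes kept 30.7% and 57.1%, though inflamed arrays also held 62.8%, 63.3% and 69.8% for them. Both sets rose at least 2-fold, but the Wnt genes were taken by arrays apart from normal and the 38 by adjusted p. That adjusted p rests on a spread that includes the 2 arrays, so genes low in them passed less readily. The shares of the 38 can be raised by this choice. The 12 of the 38 that inflamed mucosa does not raise kept 17.8% (quartiles 9.06% and 35.3%) and 6.73% (quartiles 1.99% and 51.7%). The same limit holds for them, so dilution stays open. Other open explanations are a sample of inflamed or regenerating mucosa, a single wrong label, or lesions that may differ in Wnt activity, which was not tested. Over all genes, r with the normal mean was 0.977 in LGD replicate 3, against 0.889 and 0.940 in LGD replicates 1 and 2. In HGD 8-week replicate 1 it was 0.928, against 0.874 and 0.931 in replicates 2 and 3. The 2 arrays need not share 1 explanation.

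For the fall of goblet and colonocyte genes at 2 weeks, degraded RNA is argued against by a Gapdh ratio that differed from normal by -0.00464 and a beta-actin ratio that differed by -0.15, although the 18S control signal also differed, by -1.64. Loss of epithelial cells from the sample is a candidate explanation, since the 15 general epithelial genes had a median log2 change of -3.03 beside -3.93 for the goblet list, and lower expression within surviving cells stays open. A lower epithelial share as the only change is argued against, because markers of other cell types moved apart by 5.20, from 4.64 for neutrophils to -0.56 for smooth muscle. Between them lay macrophages at 2.25, extracellular matrix at 1.47, endothelium at 1.28, neurons and glia at 1.22 and T cells at 0.70. The gap rests on the outer lists, and the neutrophil rise was already known. A lower epithelial share as part of the change, also in the lists that rose, stays open.

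Other splits of the same arrays were counted. For the F test 1 of 100 splits, the real one, gave as many as 5840 genes, and the highest other gave 4058, which argues against chance. A count so high in another split points to structure among the arrays. Inflamed mucosa by itself gave 6034 genes against normal mucosa, so the F test count says little about whether the later stages differ. For genes changed one way in all 5 stages, 1 of 100 gave as many as 36 and the highest other gave 4. Other splits mix inflamed arrays into several groups, which can raise the spread within groups. Few genes can then pass in all 5 comparisons, so the low counts of these splits do not exclude chance. These splits remove the stage effects, so overlap that arises through the shared controls among genes changed in some stages is not excluded, and the count ran from 3 to 101 when single arrays were left out. For single comparisons 6 arrays make 10 splits, too few for a share under 0.05. Each other split again mixes arrays of both groups, which puts a difference between them into the spread within groups. Low counts in the other splits therefore do not exclude chance. The real split gave more genes than any other for inflamed mucosa (6034, highest other 0), LGD (733, highest other 2), HGD at 6 weeks (147, highest other 0), HGD at 8 weeks (1451, highest other 1), carcinoma (116, highest other 0) and LGD against inflamed mucosa (4678, highest other 101). For the 4 comparisons with 0 genes, 10 of 10 splits gave as many, and the highest others were 0 for HGD at 6 weeks against LGD, 1 for HGD at 8 against 6 weeks, and 4 and 1 for carcinoma against HGD at 8 and 6 weeks.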
